A study of Mus musculus with 16 samples.

How the data were processed

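The data were bulk RNA sequencing libraries of total RNA from gonadal white adipose tissue of female C57BL/6 mice, a standard inbred laboratory strain. Although the series is titled as single-cell work, each deposited library is 1 column of gene counts with no cell barcodes, so it was analysed as bulk RNA. Control mice (C) were compared with mice that had been separated from the dam each day during suckling and weaned early (MS), a model of early life stress. The mice were then fed a high-fat (HF) or low-fat (LF) diet. Per the labels, fresh tissue was digested with collagenase, the floating mature adipocyte fraction (A) was parted from the stromal vascular fraction by centrifugation and filtration, and magnetic sorting was used to enrich adipocyte lineage cells, including the preadipocytes (P). The antibodies used in the sort are not given in the sources used here. Sequencing was paired-end on an Illumina NovaSeq instrument.

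Per the labels' group codes, 16 libraries fall into 6 groups: 4 control and 4 stress preadipocyte libraries on the high-fat diet, 3 control and 3 stress mature adipocyte libraries on the high-fat diet, and 1 control and 1 stress preadipocyte library on the low-fat diet. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

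The authors deposited raw read counts per gene and FPKM values (fragments scaled for gene length and sequencing depth) for 54532 Ensembl genes in each of the 16 libraries, with gene coordinates and lengths beside them. STAR 2.6.1d, DESeq2 1.20.0 and edgeR 3.24.3 are named, with the builds mm10 and GRCm38, per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes, of paralogs such as the haemoglobin genes Hba-a1 and Hba-a2 or the heat shock genes Hspa1a and Hspa1b, and of immunoglobulin segments may therefore be split or shared in the counts. Of the 54532 gene IDs, 54409 also appear in the GENCODE M21 name table, and there was no line without a gene ID. Coordinates are those in the deposited tables, on GRCm38. The deposited FPKM values equal the count divided by gene length and library total, times 1 factor per library. That factor was the inverse of the DESeq2-type size factor relative to library size, to within a ratio of 1.0075 that was the same in every library, so the authors' FPKM were scaled between libraries.

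Library totals ran from 14182130 to 23368821 counts. Preadipocyte libraries held 23004 to 26053 detected genes and mature adipocyte libraries 15344 to 20964. The number of genes with 1 to 5 counts divided by the number with 6 to 15 counts, a measure of how well rare transcripts were sampled, was 1.82 to 2.23 in preadipocytes. In control mature adipocyte libraries 1, 2 and 3 it was 1.15, 1.84 and 0.637, and in the stress adipocyte libraries 1.55 to 2.21. Control adipocyte library 3 was also the smallest, and control adipocyte libraries 1 and 3 are called the low-complexity libraries. A gene at 0 in a library was read against a floor of 3 counts, which covers counting error only.

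Every pair of the 120 pairs of libraries was compared before averaging, over genes with a summed count of at least 20. Control high-fat preadipocyte libraries 1 and 3 had a biological coefficient of variation of 0.0427 and differed at 7.01 percent of genes, against 0.205 to 0.567 and 43.0 to 79.0 percent in the remaining 17 of 18 pairs within a group. They differed slightly more than counting noise (chi-square per gene 4.03) and far less than any other pair, so they were counted as 1 sample in every mean ± SD, where n is 3 for that group. The model fits keep both libraries, as laid down before the data were examined, and the counts with the pair summed into 1 library are given beside them.

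Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, a robust quasi-likelihood fit and the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of genes below are from this test unless another tool is named. Stress against control was fitted in the 8 high-fat preadipocyte libraries and, separately, in the 6 mature adipocyte libraries. The cell type comparison used the 14 high-fat libraries with early life treatment as a covariate, and the same libraries with an interaction term tested whether the stress effect differed between cell types. High-fat against low-fat diet was fitted in the 10 preadipocyte libraries with early life treatment as a covariate. The 2 low-fat libraries were compared with no test, as log2 ratios of CPM with a prior count of 2, over genes with at least 10 CPM in either library, and list medians were set among 10000 random lists matched on expression. CPM values per group are counts scaled to library size with TMM factors over all 16 libraries. The ± after a log2 fold change is its standard error, and the ± after a CPM mean is the SD.

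A total of 32 gene lists were fixed before the data were examined: 12 lists of cell type markers (mature adipocyte, adipocyte progenitor, macrophage, T and NK cell, B cell, neutrophil, endothelial, mural cell, mesothelial, ovary and reproductive tract, erythroid and Schwann cell) and 20 pathway lists (adipogenic transcription factors, adipogenesis repressors, triglyceride synthesis with glycerol and fatty acid uptake, de novo lipogenesis, lipolysis, fatty acid oxidation, oxidative phosphorylation, thermogenic genes, glucocorticoid and mineralocorticoid signalling, renin-angiotensin system, extracellular matrix, inflammatory cytokines, interferon response, cholesterol synthesis, cell cycle, immediate early and heat shock genes, endoplasmic reticulum stress, circadian clock, neurotrophic and sympathetic signalling, and insulin signalling). Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 32 lists of a comparison, again with the correlation estimated per list, and with fry, which tests whether the genes of a list move on balance in 1 direction. "Adjusted over the list alone" means adjustment over the members of that list.

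The genes named were chosen by a rule fixed before the data were examined. For each replicated comparison it took the 8 highest and 8 lowest fold changes among genes with adjusted p below 0.05, a mean log2 CPM of at least 2 and no overlap between the groups, leaving out gene models without a proper symbol. Where no gene passed in a direction, it took the 3 smallest p-values, said not to pass, and for each list up to 3 members that passed with the smallest p, or 1 that did not. It always took Nr3c1, Nr3c2, Hsd11b1, Lep, Adipoq, Pparg, Pnpla2, Lipe, Aqp7, Gpd1, Plin1 and Pdgfra. For the low-fat pair it took the 5 highest and 5 lowest ratios. Not every gene the rule admits is discussed. Genes chosen after their values were seen are said to be so.

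The scripts were tested on simulated data drawn from the real means and library sizes, with 200 genes changed, 100 at each of 2 sizes. The changed genes had an average log2 CPM of at least 1. All libraries were simulated as independent, the near-identical pair included, so recovery in the real data may be lower. Of the genes changed 4-fold, edgeR recovered 77.0 percent in the design for stress in preadipocytes (8 libraries, 16409 genes), 48.0 percent for stress in mature adipocytes (14064 genes), 82.0 percent for cell type (17498 genes), 29.0 percent for the interaction (17506 genes) and 62.0 percent for diet (19367 genes). Of those changed 2-fold it recovered 25.0, 1, 48.0, 1 and 12.0 percent in the same order. DESeq2 1.42.0 recovered 93.0, 71.0, 93.0, 71.0 and 90.0 percent of the genes changed 4-fold. Of those changed 2-fold it recovered 55.0, 15.0, 73.0, 11.0 and 36.0 percent. False calls numbered 8, 4, 3, 0 and 7 with edgeR, and 59, 38, 43, 39 and 63 with DESeq2.

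The alternatives set before the data were examined were DESeq2-type size factors, no filter on low counts, a filter of at least 1 CPM, DESeq2's Wald test, limma on the authors' FPKM with a pseudocount of 1 or 0.1 and with or without a filter on mean FPKM of at least 0.5, each library left out in turn, the replicate number as a block, a fit of all 16 libraries, 1 surrogate variable (sva 3.50.0), and the cell type contrast in control or stress libraries alone. Alternatives chosen after the data were seen were the near-identical pair as 1 library, the low-complexity control adipocyte libraries left out together, the 2 stress preadipocyte libraries with the highest macrophage scores left out, and a macrophage score as a covariate. Splits of the samples into other groups of the same sizes were counted, with up to 100 drawn.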

Results

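RNA was profiled in preadipocytes and mature adipocytes of gonadal white fat from female mice raised undisturbed or under early life stress, that is, daily separation from the dam and early weaning. On the high-fat diet there were 4 control and 4 stress preadipocyte libraries and 3 control and 3 stress mature adipocyte libraries. On the low-fat diet there was 1 preadipocyte library of each kind. Library totals ran from 14182130 counts (control adipocyte library 3) to 23368821 (the low-fat control library). Control high-fat preadipocyte libraries 1 and 3 were nearly identical, differing at 7.01 percent of genes against at least 43.0 percent in every other pair within a group, and were counted as 1 sample in the means, so that n = 3 there.

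The comparison of cell types asked how the transcriptome of mature adipocytes differed from that of preadipocytes on the high-fat diet. Genes of the lipid-storing cell dominated the mature fraction. Cfd, which encodes the adipokine adipsin, was 292-fold higher (log2 fold change 8.19 ± 0.85, adjusted p = 7.84e-07), and Cyp2e1, a cytochrome P450, was also 292-fold higher (8.19 ± 0.78). Adig, encoding adipogenin, was 184-fold higher, Retn, encoding resistin, 173-fold, Cidec, a lipid droplet fusion protein, 164-fold, and Pck1, the glyceroneogenic enzyme, and the carboxylesterase Ces1f each 155-fold. Adipoq, encoding adiponectin (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028), averaged 24.9 ± 4.20 CPM in control preadipocytes (n = 3) and 4382 ± 2522 CPM in control adipocytes (n = 3), 148-fold higher in the fit. Lep, encoding leptin, was 70.5-fold higher (adjusted p = 3.41e-06), and Plin1, encoding the droplet coat protein perilipin, 87.0-fold higher.

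In the opposite direction, the long non-coding RNA Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726) was 112-fold lower in mature adipocytes (log2 fold change -6.81 ± 0.56, adjusted p = 7.87e-08). The hyaluronan synthase Has2 was 88.7-fold lower, the neuronal pentraxin Nptx2 76.2-fold, the metalloproteinase Adamts16 64.9-fold, the guidance cue Sema3d 47.3-fold, the microfibril gene Fbn1 43.7-fold, Fndc1 42.7-fold and the cell adhesion gene Opcml 40.8-fold. Pdgfra, the receptor that marks adipocyte progenitors (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), averaged 631 ± 230.5 CPM in control preadipocytes and 24.4 ± 16.8 CPM in control adipocytes, 26.0-fold lower (adjusted p = 3.53e-08).

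The fixed gene lists described the same difference. All 20 measured mature adipocyte markers were higher in mature adipocytes (median log2 fold change 6.26), among them Gpd1, the glycerol-3-phosphate dehydrogenase (7.07 ± 0.32), Lipe, hormone-sensitive lipase (6.02 ± 0.31), and Acsl1, which activates fatty acids (6.21 ± 0.32). Of 23 lipolysis genes 19 were higher and 2 lower, including Pnpla2, the adipose triglyceride lipase (5.68 ± 0.27), Mgll, monoglyceride lipase (4.64 ± 0.20), and Prkar2b, a protein kinase A subunit (4.89 ± 0.25). For de novo lipogenesis 14 of 16 genes were higher, led by the desaturase Scd1 (6.34 ± 0.37), fatty acid synthase Fasn (4.53 ± 0.21) and the citrate carrier Slc25a1 (4.49 ± 0.18). Of 22 genes of triglyceride synthesis and uptake 19 were higher and 3 lower, with the acyltransferase Agpat2 at 5.84 ± 0.26 and the glycerol channel Aqp7 at 4.42 ± 0.28. Fatty acid oxidation was higher in 17 of 19 genes, for example Hadh (3.68 ± 0.20). These 5 lists passed camera also with an estimated correlation, at adjusted p = 0.0163, 0.0140, 0.00549, 0.0163 and 0.0278 in that order. Their counts were the same adjusted over the list alone.

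Oxidative phosphorylation was higher in 30 of 30 genes, for example Cyc1 (3.22 ± 0.22) and Atp5b (2.50 ± 0.18), though adjusted p = 0.153 with an estimated correlation. Thermogenic genes had 8 of 12 higher and 1 lower, with Cidea, a brown and beige fat gene, at 7.54 ± 0.79 and Cox8b at 5.99 ± 0.56 (adjusted p = 0.430 with an estimated correlation). The thermogenic list did not pass in control libraries only (1.36), without control adipocyte library 2 (2.42) or at 1 CPM (1.72). Cholesterol synthesis had 10 of 20 higher, such as Nsdhl (2.87 ± 0.20) and Lss (2.92 ± 0.23), and 4 lower (adjusted p = 0.354 with an estimated correlation). The list of neurotrophic and sympathetic signalling had 8 higher and 7 lower of 18. Among the higher were the monoamine transporter Slc22a3 (6.37 ± 0.40) and the neuregulin Nrg4 (5.19 ± 0.34), with adjusted p = 0.354 with an estimated correlation. In stress libraries only this list (0.99) did not pass, nor did it at 1 CPM (0.58). Adipogenic transcription factors split 8 higher, among them Cebpa (3.69 ± 0.24), Pparg (2.67 ± 0.21) and Srebf1 (2.42 ± 0.20), and 6 lower of 16 (adjusted p = 0.481 with an estimated correlation).

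Of 20 progenitor markers 19 were lower in mature adipocytes and 1 higher, with Dpp4 at -4.90 ± 0.27 and Mfap5 at -4.58 ± 0.34 (adjusted p = 0.153 with an estimated correlation). Extracellular matrix genes were lower in 24 of 26 and higher in 1, such as the metalloproteinases Mmp2 (-4.38 ± 0.35) and Mmp14 (-3.83 ± 0.30), with adjusted p = 0.354 with an estimated correlation. Among 27 inflammatory genes 19 were lower, including the prostaglandin synthase Ptgs2 (-4.73 ± 0.42), the eosinophil chemokine Ccl11 (-3.32 ± 0.30) and the alarmin Il33 (-3.53 ± 0.22), with adjusted p = 0.354 with an estimated correlation. Immediate early and heat shock genes, which respond to dissociation of tissue, were lower in 16 of 22 and higher in 2, for example Nr4a1 (-2.15 ± 0.18) and Nr4a3 (-3.51 ± 0.27), with adjusted p = 0.354 with an estimated correlation. Adipogenesis repressors were lower in 10 of 13, with Wnt10b at -5.02 ± 0.52 and Zfp521 at -2.95 ± 0.31 (adjusted p = 0.419 with an estimated correlation), and did not pass in stress libraries only (-0.87).

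Markers of other cell types differed between the fractions as well. Endothelial markers were higher in mature adipocytes in 12 of 16 genes and lower in 2 (Cldn5 2.91 ± 0.45, Sox18 3.13 ± 0.48), with adjusted p = 0.564 with an estimated correlation, and did not pass in control libraries only (1.40). Mural cell markers were higher in 7 of 12 (Mcam 3.67 ± 0.40, Acta2 2.99 ± 0.47), with adjusted p = 0.481 with an estimated correlation. T and NK cell markers were lower in 15 of 18, with adjusted p = 0.481 with an estimated correlation. B cell markers were lower in 12 of 14 and higher in 1 (Igkc -2.62 ± 0.42), with adjusted p = 0.588 with an estimated correlation. All 11 mesothelial markers were lower (Wt1 -4.70 ± 0.39), with adjusted p = 0.490 with an estimated correlation, as were 8 of 9 ovary and reproductive tract markers (Ovgp1 -3.60 ± 0.68), with adjusted p = 0.354 with an estimated correlation. Macrophage markers had a median of -0.05 (adjusted p = 0.870), with Lgals3 higher (1.44 ± 0.37) and Cd163 lower (-1.25 ± 0.50) among 20. Neutrophil (-1.02, adjusted p = 0.492), erythroid (-1.05, adjusted p = 0.413) and Schwann cell markers (-0.05, adjusted p = 0.870) did not pass.

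Genes of corticosteroid signalling, of interest in a stress model, went both ways, with 3 higher and 9 lower of 18 (median -0.74, adjusted p = 0.179, so the list did not pass). Nr3c1, the glucocorticoid receptor (ENSMUSG00000024431, chromosome 18, 39410545 to 39491301), was 1.55-fold lower in mature adipocytes (adjusted p = 0.00907), and Hsd11b1, which regenerates active corticosterone, was 3.49-fold lower (adjusted p = 0.000210). Their targets Sgk1 (-1.38 ± 0.19) and Dusp1 (-1.04 ± 0.15) were lower, while the mineralocorticoid receptor Nr3c2 stood at -0.27 ± 0.28 (adjusted p = 0.414). In the renin-angiotensin list (median -1.27, adjusted p = 0.310, 2 higher and 7 lower of 11) angiotensinogen, Agt, was 25.5-fold higher and the converting enzyme Ace 8.11-fold lower. The insulin signalling list did not pass (median 0.40, adjusted p = 0.0634), although the glucose transporter Slc2a4 was 82.2-fold higher. The circadian clock (-0.63, adjusted p = 0.281), interferon response (-0.02, adjusted p = 0.771), cell cycle (0.24, adjusted p = 0.870) and endoplasmic reticulum stress lists (0.14, adjusted p = 0.413) did not pass either.

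In all, 11372 of 18194 genes passed, 5035 higher and 6337 lower in mature adipocytes, and 8392 of them differed at least 2-fold. With the near-identical pair as 1 library the count was 10740 (4832 higher, 5908 lower). The lists called numbered 21 of 32 with the preset correlation, 5 with an estimated correlation and 26 with fry. With the near-identical pair as 1 library 19 passed, without B cell markers (adjusted p = 0.0529, held in 8 of 22 alternatives) and adipogenic transcription factors (adjusted p = 0.0510, held in 9 of 22). The counts adjusted over the list alone differed for T and NK cell markers (16 lower), adipogenic transcription factors (7 lower), repressors (1 higher), macrophage (0 lower), neutrophil (1 lower, against 2 over all genes) and erythroid markers (0 lower, against 2). They also differed for the renin-angiotensin list (8 lower), the interferon response (1 higher and 4 lower, against 4 and 6) and endoplasmic reticulum stress (8 higher, against 7). The median over all genes was -0.24 on the log2 scale. The fold changes are therefore relative to a scaling in which the median gene lay slightly lower in mature adipocytes.

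**Figure D1:**
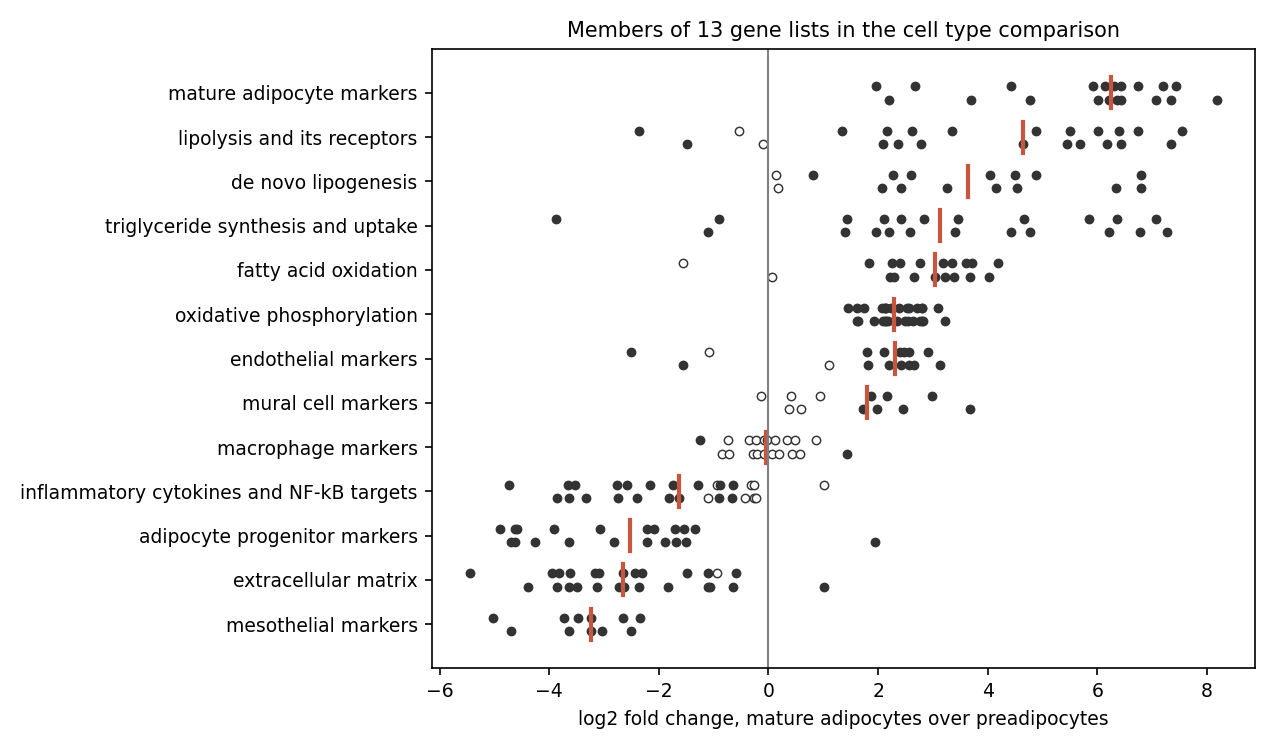
Log2 fold changes (mature adipocytes over preadipocytes) of the members of 13 gene lists in the 14 high-fat libraries, with filled points for adjusted p below 0.05 and a bar at each list's median. The median of the mature adipocyte markers lies at 6.26 and that of the mesothelial markers at -3.24.

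Whether early life stress changed preadipocytes on the high-fat diet was asked next. Endothelial markers lay lower in the stress libraries, with 16 of 16 negative and a median log2 fold change of -1.37. The groups overlapped: endothelial scores were 5.59 and 5.56 (mean log2 CPM) in the near-identical control pair, 4.08 and 4.46 in control libraries 2 and 4, 4.52 in stress library 1 and 2.99 to 3.71 in the other stress libraries. With the pair as 1 library the median was -1.11. The transcription factor Sox18 averaged 6.41 ± 3.87 CPM in controls (n = 3) and 2.58 ± 0.91 CPM under stress (n = 4). B cell markers were lower in 14 of 14 (median -1.10), with the surface antigen Ms4a1 at 18.2 ± 8.13 and 5.24 ± 3.54 CPM. Mesothelial markers were lower in 11 of 11 (-1.08), with the keratin Krt18 at 84.9 ± 103.7 and 19.8 ± 12.6 CPM. The groups overlapped here too, with mesothelial scores of 6.57, 6.13, 6.58 and 3.58 in controls and 5.56, 5.53, 2.07 and 2.68 under stress. These 3 lists passed camera with the preset correlation, at adjusted p = 5.67e-14, 4.46e-12 and 1.96e-05, and each had adjusted p = 0.627 with an estimated correlation. Of the 16 endothelial markers 12 were lower adjusted over the list alone, and 0 of the B cell or mesothelial markers passed. The endothelial count takes the near-identical pair, which had the highest endothelial scores, as 2 libraries. It was not made with the pair as 1 library.

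Macrophage and cell cycle genes leaned the other way. Macrophage markers were positive in 18 of 20 (median 0.60), with Gpnmb, a gene of lipid-associated macrophages, at 289 ± 99.6 CPM in controls and 914 ± 660 CPM under stress, and adjusted p = 0.658 with an estimated correlation. Cell cycle genes were positive in 29 of 29 (median 0.85), with the mitotic gene Birc5 at 4.29 ± 1.07 and 10.4 ± 7.64 CPM, and adjusted p = 0.627 with an estimated correlation. The macrophage scores of stress libraries 3 and 4 were 8.36 and 8.54 (mean log2 CPM), against 7.03 and 5.68 in stress libraries 1 and 2 and 6.09 to 7.48 in controls. The macrophage call held in 10 of 16 alternatives and was lost without control library 2 (0.35), stress library 3 (0.36) or stress library 4 (0.19). The cell cycle call held in 13 of 16 and was lost without stress library 4 (0.45). With 1 surrogate variable neither list passed (-0.27 and 0.03). Without libraries 3 and 4, chosen after the data were seen, the medians were -0.68 for macrophage markers, -0.48 for cell cycle genes, -1.2 for endothelial markers, -1.22 for B cell markers and -0.19 for mesothelial markers, which no longer passed. Krt18 was accompanied by Krt8 at 235 and 226 CPM in the near-identical control pair. That pair also held the bladder epithelial transcript Upk1a (140 and 144 CPM). Whether the keratins there came from mesothelial cells was not tested.

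A further 7 lists passed with the preset correlation, each beside those shifts in macrophage and endothelial markers. Immediate early and heat shock genes were negative in 21 of 22 (median -0.35), with the co-chaperone Dnajb1 at 257 ± 8.03 and 188 ± 41.9 CPM. T and NK cell markers (-0.46, with the adhesion receptor Cd2 at -0.98 ± 0.50), erythroid markers (-0.77, with the globin Hbb-bs at -0.93 ± 0.59) and adipogenesis repressors (-0.31, with Dlk1, the preadipocyte factor, at -1.38 ± 0.41) were lower. Cholesterol synthesis (0.27) and extracellular matrix (0.22, with the protease inhibitor Timp1 at 1.38 ± 0.45) were higher, and these 6 lists had adjusted p = 0.627 with an estimated correlation. Extracellular matrix scores were 9.61 and 9.60 in the near-identical control pair and 10.59 and 10.45 in control libraries 2 and 4. Under stress they were 10.05 to 10.63, so only the pair lay lower. With the pair as 1 library, camera with the preset correlation gave this list adjusted p = 0.0358. The interferon response was higher in 22 of 24 (0.23, with the nucleic acid sensor Zbp1 at 0.79 ± 0.31), with adjusted p = 0.658 with an estimated correlation. Without stress library 2 the T and NK cell (-0.17) and erythroid lists (-0.48) did not pass, and without control library 4 the erythroid list (-0.39) did not. T and NK cell medians ran from -1.49 to -0.17 over the alternatives. Their score was 3.77 in stress library 1, 1.48 to 2.10 in the other stress libraries and 1.79 to 3.40 in controls. The interferon call held in 10 of 16 alternatives (medians 0.13 to 0.44) and was lost without control library 2 or stress library 1 or 3 (0.15, 0.13 and 0.14). Repressors (0.07), cholesterol synthesis and extracellular matrix did not pass without libraries 3 and 4. Adjusted over the list alone, 0 members of these 7 lists, of the macrophage list or of the cell cycle list passed.

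No single gene passed the adjustment. edgeR called 0 of 16810 genes, with 1010 at an unadjusted p below 0.05 and a smallest adjusted p of 0.79997, while DESeq2 called 27 (5 higher, 22 lower) and limma on FPKM 0. fry called 0 lists here (smallest adjusted p = 0.529), and camera 15 in place of 12 with the near-identical pair as 1 library. With the near-identical pair as 1 library edgeR called 0, with 496 unadjusted. The smallest p-values belonged to Sorcs2, a sortilin family receptor (10.8 ± 1.70 CPM in controls and 4.88 ± 1.08 under stress), the signalling ligand Wnt4 (9.43 ± 3.99 and 3.04 ± 0.91) and the zinc finger gene Zfp827 (10.01 ± 0.67 and 4.48 ± 1.44) among lower genes. Among higher ones they belonged to Hhipl1 (27.6 ± 5.13 and 46.5 ± 7.04), the RNA-binding gene Igf2bp2 (21.6 ± 1.45 and 36.5 ± 8.79) and the mucin Muc6 (3.48 ± 0.16 and 7.05 ± 1.47). Nr3c1 was 185 ± 16.3 CPM in controls and 174 ± 10.4 under stress (log2 fold change -0.09 ± 0.10, adjusted p = 0.886), and Hsd11b1 66.4 ± 17.8 and 63.8 ± 37.3. Dusp1 (-0.41 ± 0.16), the insulin-regulated factor Foxo1 (-0.61 ± 0.24), Aqp7 (-0.97 ± 0.37), Gpd1 (0.72 ± 0.32) and Pdgfra (0.10 ± 0.28) did not pass either. The remaining genes named in advance lay between -0.34 (Nr3c2) and 0.57 (Plin1). Lep stood at 0.32 ± 0.90, Adipoq at -0.16 ± 0.89, Pparg at -0.11 ± 0.29, Pnpla2 at 0.16 ± 0.16 and Lipe at -0.31 ± 0.24.

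**Figure D2:**
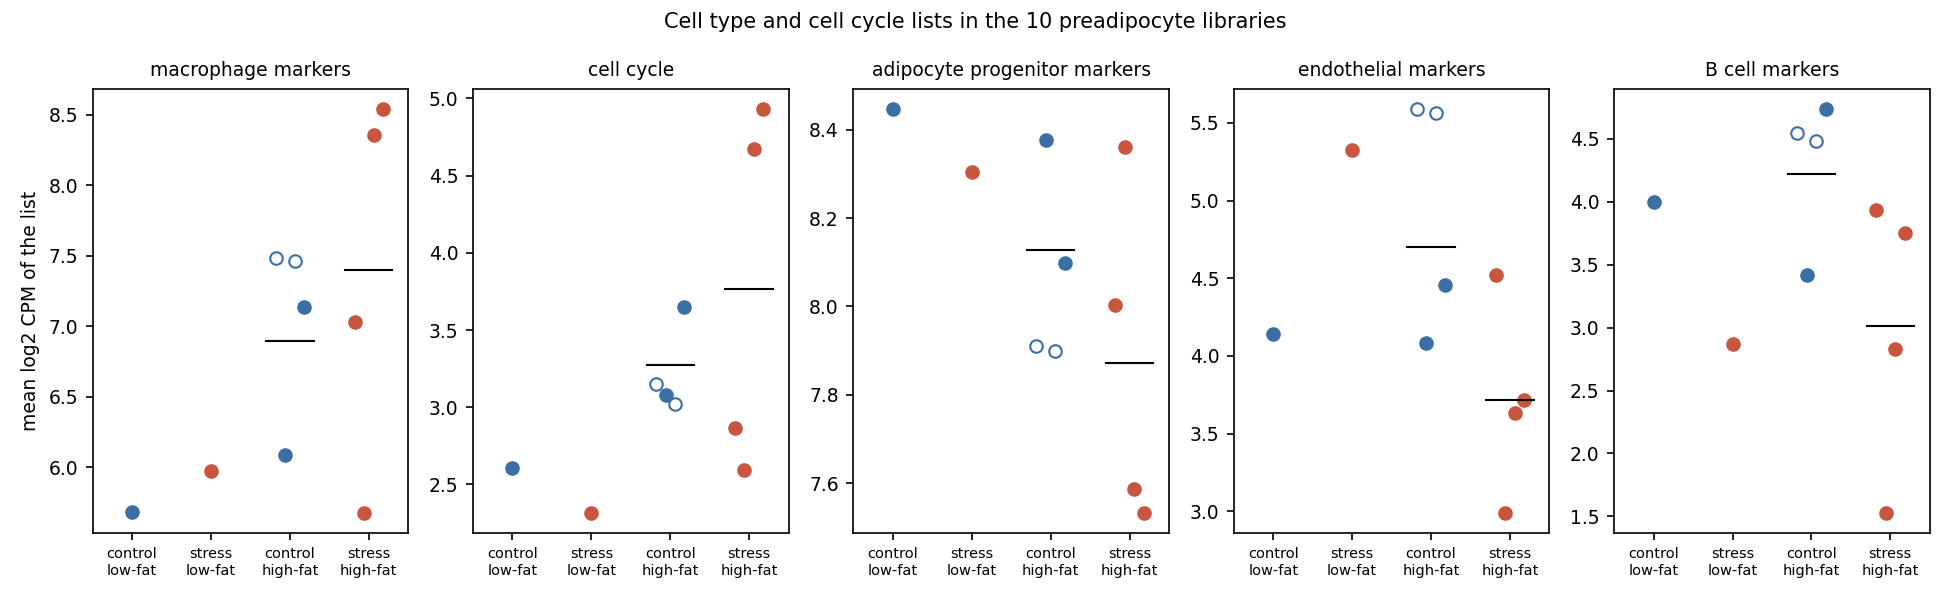
Mean log2 CPM of 5 gene lists in each of the 10 preadipocyte libraries (blue control, red early life stress), with open circles for the near-identical pair and a line at each high-fat group's mean, the pair counted once. Macrophage scores run from 5.68 to 8.54, and stress libraries 3 and 4 are the highest in the macrophage and cell cycle panels.

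In mature adipocytes the question was the same. Thermogenic genes lay higher under stress, with 11 of 12 positive and a median log2 fold change of 1.59 (1.05 to 2.54 over the alternatives). Control library 2 scored 3.39 (mean log2 CPM), near the 3.84 to 4.36 of the stress libraries, against 1.70 and 0.687 in control libraries 1 and 3. Dio2, the deiodinase that activates thyroid hormone (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438), averaged 2.18 ± 1.63 CPM in controls (n = 3) and 15.7 ± 10.2 CPM under stress (n = 3). Ucp1, the uncoupling protein of brown and beige fat (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), averaged 17.0 ± 24.6 and 223 ± 86.3 CPM, Cidea 14.1 ± 14.2 and 51.8 ± 40.0, and the elongase Elovl3 5.74 ± 9.41 and 48.3 ± 30.6; these 3 genes were chosen after their values were seen. The list passed camera with the preset correlation (adjusted p = 2.51e-10), with adjusted p = 0.648 with an estimated correlation, and adjusted over the list alone 2 of 12 members were higher. Library quality moved with the group: in the low-complexity control libraries 1 and 3 Ucp1 was 5.28 and 0.48 CPM, in control library 2 it was 45.3 CPM, and in the stress libraries it was 132 to 304 CPM. With libraries 1 and 3 left out, chosen after the data were seen, the list's median was 1.23, but that fit has 1 control library and its spread comes from the stress libraries alone.

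**Figure D3:**
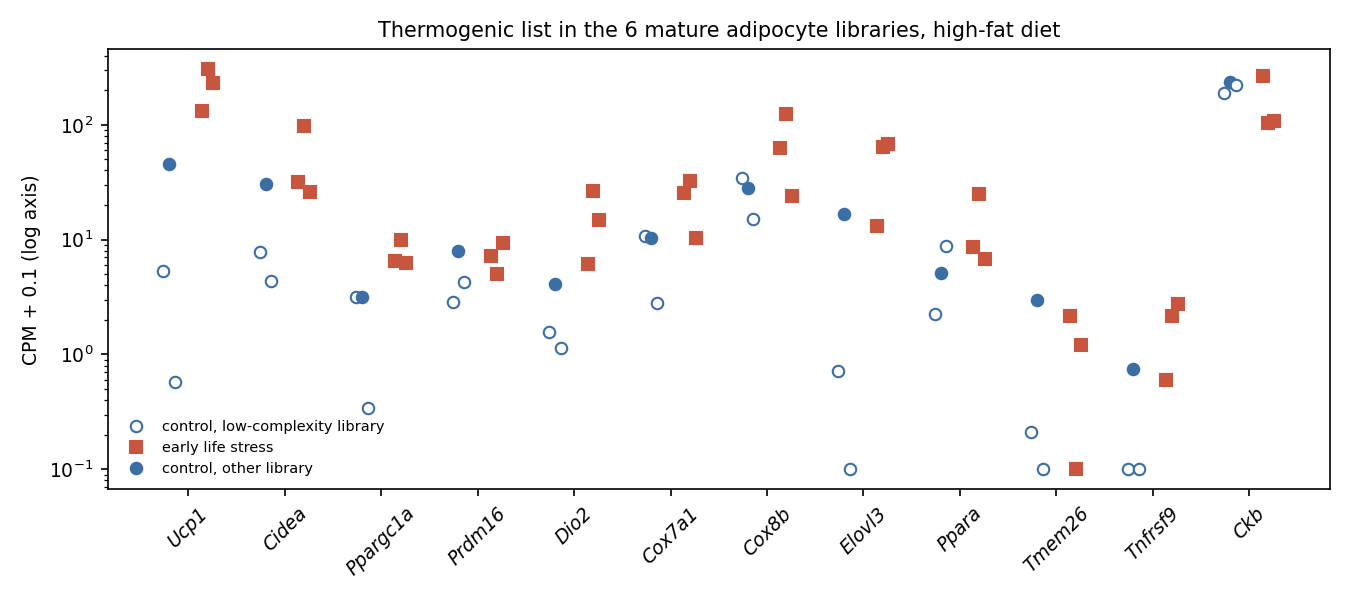
CPM plus 0.1 on a log axis for the 12 measured thermogenic genes in each of the 3 control (circles, open for the low-complexity libraries) and 3 stress (squares) mature adipocyte libraries. For Ucp1 the stress libraries lie between 132 and 304 CPM and the controls between 0.48 and 45.3 CPM, and Ckb is the gene with a negative fold change.

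The other lists that passed with the preset correlation, each with adjusted p = 0.648 with an estimated correlation, shifted less. Higher were erythroid markers (median 0.78, with the globin Hbb-bt at 17.9 ± 5.13 CPM in controls and 42.6 ± 30.5 under stress), endoplasmic reticulum stress (0.38, with the chaperone Hsp90b1 at 263 ± 119 and 600 ± 249) and the interferon response (0.29, with the protease Usp18 at 4.14 ± 2.26 and 10.3 ± 4.97). Triglyceride synthesis and uptake was higher too (16 of 22, median 0.37, mean 0.01), with Acsl1 at 1809 ± 303 and 4197 ± 2653 CPM. Its water and glycerol channel Aqp3 was 12.5 and 6.14 CPM in control libraries 1 and 3, which also held bladder epithelial transcripts such as Upk1a (67.4 and 26.1 CPM), and 1.24 CPM in control library 2. It averaged 6.63 CPM in controls and had 0 counts in all 3 stress libraries, at least 121.5-fold lower against a floor of 3 counts over the group. The list's median is 0.37 also with Aqp3 at that bound. Lower were inflammatory genes (19 of 27, median -0.41, with Tnf at 101 ± 51.3 and 56.4 ± 14.1 CPM) and extracellular matrix (17 of 26, -0.28, with the matrix glycoprotein Tnc at 30.0 ± 5.56 and 10.8 ± 4.52 CPM). Of 12 alternatives the call held in 10 for inflammatory genes, 9 each for endoplasmic reticulum stress and triglycerides, 8 for extracellular matrix, 7 for the interferon response and 6 for erythroid markers (medians 0.12 to 1.42). Inflammatory scores were 5.48, 5.43 and 5.40 in controls and 4.05, 5.70 and 5.73 under stress, so stress library 1 alone lay lower. Without control library 2, 0 of these 6 lists passed. Without stress library 1, inflammatory genes (-0.06), extracellular matrix (-0.38) and erythroid markers (0.12) did not pass. Without stress library 2, triglycerides (0.03), endoplasmic reticulum stress (0.27), extracellular matrix (-0.16) and the interferon response (0.22) did not. The interferon response was also lost without control library 1 (0.39) or stress library 3 (0.23), erythroid markers without control library 1 (0.64) and extracellular matrix without control library 3 (-0.06). The macrophage scores beside them were 6.37, 8.34 and 6.98 in controls and 7.49, 6.48 and 7.34 under stress. Adjusted over the list alone, 1 member of the triglyceride list was lower and 0 of the other 5 lists passed.

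Again no single gene passed: edgeR called 0 of 14485 genes, with 417 at an unadjusted p below 0.05 and a smallest adjusted p of 0.99959, DESeq2 called 9 (1 higher, 8 lower) and limma on FPKM 0. With no filter on low counts edgeR called 51 (14 higher, 37 lower), and without control library 2 it called 9 (0 higher, 9 lower). The controls left in that last fit are the low-complexity libraries 1 and 3. These also held epithelial transcripts such as Krt15 (23.3 and 9.74 CPM, against 0 CPM under stress). Whether the calls follow that was not tested. The lists called numbered 7, but 3 without control library 2, 12 or 13 without control library 1 or 3, and 13 without stress library 3, and fry called 0 (smallest adjusted p = 0.722). Smallest p-values were those of the prolactin receptor Prlr (12.4 ± 3.67 and 34.2 ± 5.84 CPM), the fatty acid carrier Fabp3 (5.30 ± 4.63 and 30.5 ± 18.0) and Dio2 among higher genes. Among lower ones they were those of the choline kinase Chka (61.5 ± 9.42 and 24.8 ± 7.13), the EGF receptor inhibitor Errfi1 (239 ± 84.6 and 91.3 ± 18.3) and the growth factor Hbegf (33.8 ± 7.03 and 12.5 ± 2.56). Lep averaged 3044 ± 2079 CPM in controls and 1312 ± 658 under stress (log2 fold change -1.27 ± 0.54, adjusted p = 0.99959). Nr3c1 was 83.6 ± 29.2 and 147 ± 28.9 CPM (0.74 ± 0.35) and Hsd11b1 24.7 ± 9.02 and 13.8 ± 3.17 CPM (-0.92 ± 0.39), neither past the threshold. The corticosteroid list did not pass in adipocytes (median -0.09, adjusted p = 0.459) or in preadipocytes (0.05, adjusted p = 0.172). Acacb, an acetyl-CoA carboxylase (1.63 ± 0.59), Plin5, which ties droplets to mitochondria (1.25 ± 0.45), and Krt18 (-3.82 ± 1.10) did not pass. Gpd1 (0.39 ± 0.41), Adipoq (-0.74 ± 0.52), Pparg (0.00 ± 0.35), Pnpla2 (-0.33 ± 0.46), Lipe (-0.17 ± 0.48), Aqp7 (-0.01 ± 0.32), Plin1 (0.13 ± 0.43), Nr3c2 (0.18 ± 0.46) and Pdgfra (-0.35 ± 0.51) did not pass either.

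The interaction tested directly whether the stress effect differed between the cell types; positive values mean a more positive stress effect in mature adipocytes. The thermogenic list had the highest median, 2.62 with 11 of 12 positive (1.69 to 4.24 over the alternatives, the highest without control adipocyte library 2), and Dio2 averaged 3.19 ± 2.71 CPM in control and 1.09 ± 1 in stress preadipocytes against 2.18 and 15.7 CPM in adipocytes (interaction 4.58 ± 1.23). It passed camera with the preset correlation, with adjusted p = 0.241 with an estimated correlation. Endothelial markers (1.54, 16 of 16 positive, Sox18 1.98 ± 0.78), B cell markers (1.34, 14 of 14, Ms4a1 3.94 ± 1.07), erythroid markers (1.58, 7 of 7) and de novo lipogenesis (0.37, 11 of 16, Acacb 2.35 ± 0.68) were higher, with adjusted p = 0.584 with an estimated correlation for each. Adipogenesis repressors were higher (0.76, with the nuclear receptor Nr2f2 at 1.2 ± 0.44), with adjusted p = 0.626 with an estimated correlation. Extracellular matrix (-0.56, 23 of 26 negative, Tnc -2.26 ± 0.63), macrophage markers (-0.94, 18 of 20 negative, with the integrin Itgax at -1.56 ± 0.81) and inflammatory genes (-0.50, 18 of 27 negative) were lower, with adjusted p = 0.653 with an estimated correlation for each. In the inflammatory list the B cell chemokine Cxcl13 was positive (2.23 ± 0.87). Cell cycle genes were lower (-0.88, 28 of 29 negative, with the replication gene Mcm7 at -0.95 ± 0.48), with adjusted p = 0.784 with an estimated correlation. Their median ran from -2.06 to 0.27 over the alternatives and turned positive, to 0.27, without control adipocyte library 2. Over the alternatives the medians of extracellular matrix ran from -0.87 to -0.32, of macrophage markers from -1.69 to -0.18, of inflammatory genes from -0.66 to -0.22 (-0.22 without stress adipocyte library 1), of repressors from 0.41 to 1.05 and of lipogenesis from 0.19 to 0.54. The extracellular matrix call held in all 20 alternatives, though the near-identical control pair had the lowest matrix scores of the preadipocyte libraries. The cell cycle call held in 15 of 20. The count was 14 for macrophage markers and for repressors, 13 for inflammatory genes and 16 for lipogenesis. Cell cycle genes did not pass with the replicate block, without stress preadipocyte library 3 or 4, or without control or stress adipocyte library 2. Adjusted over the list alone, 3 lipogenesis genes, 2 thermogenic and 2 B cell genes were higher, and 0 members of the other 7 lists passed.

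For single genes edgeR found 0 interactions among 18194, with 1223 at an unadjusted p below 0.05 (873 with the near-identical pair as 1 library) and a smallest adjusted p of 0.717, while DESeq2 called 25 (13 positive, 12 negative) and limma on FPKM 0. fry called 0 lists (smallest adjusted p = 0.117). Without control adipocyte library 2 edgeR called 3 genes and camera 5 lists in place of 10, and without stress preadipocyte library 3 or 4, or stress adipocyte library 2, camera called 6. The smallest p-values were those of the kinase-like gene Trib2 (3.05 ± 0.69), the ERK phosphatase Dusp6 (1.76 ± 0.41) and the phosphatase Ptpn4 (1.08 ± 0.26), and of the lipopolysaccharide-binding protein Lbp (-2.25 ± 0.60), Adam23 (-1.82 ± 0.49) and the sphingosine kinase Sphk1 (-1.60 ± 0.43). Nr3c1 stood at 0.83 ± 0.32 (adjusted p = 0.735), Lep at -1.64 ± 1.2, Hsd11b1 at -0.81 ± 0.61 and Aqp7 at 0.95 ± 0.46. Nr3c2 (0.51 ± 0.55), Adipoq (-0.61 ± 1.18), Pparg (0.12 ± 0.41), Pnpla2 (-0.48 ± 0.47), Lipe (0.14 ± 0.54), Gpd1 (-0.34 ± 0.53), Plin1 (-0.43 ± 0.58) and Pdgfra (-0.44 ± 0.60) did not pass.

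The diet comparison set the 8 high-fat preadipocyte libraries against the 2 low-fat ones. Mmp12, a macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), was 1.90 and 2.68 CPM in the low-fat control and stress libraries and 114 ± 45.4 (n = 3) and 231 ± 128 CPM (n = 4) in the high-fat ones, 74.0-fold higher in the fit (adjusted p = 0.0653). The noradrenaline transporter Slc6a2 (ENSMUSG00000055368, chromosome 8, 92960079 to 93001667) was 39.7 and 52.3 CPM on the low-fat diet and 11.8 ± 2.98 and 9.30 ± 2.97 CPM on the high-fat diet, 4.50-fold lower (adjusted p = 0.0653). Macrophage markers were higher on the high-fat diet in 19 of 20 (median 1.54, 3 adjusted over the list alone), with Itgax 11.4-fold higher, and cell cycle genes were higher in 28 of 29 (1.16, with the replication clamp Pcna 1.72-fold higher, 0 adjusted over the list alone). Both lists passed with the preset correlation and had adjusted p = 0.632 with an estimated correlation. With a macrophage score as a covariate, chosen after the data were seen, the medians were 0.12 for cell cycle genes, -0.16 for macrophage markers, 0.02 for progenitor markers and -0.31 for adipogenesis repressors. None of these 4 lists passed there, nor did cholesterol synthesis, triglycerides or oxidative phosphorylation. The covariate is the score of the macrophage list itself, so the loss of that list was fixed in advance. Progenitor markers follow the score at r = -0.986 over 9 preadipocyte samples, so their loss decides nothing either.

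Beside this shift in macrophage markers, other lists passed with the preset correlation. Mature adipocyte markers were positive in 18 of 20 (0.76, Plin4 1.35 ± 0.34) and progenitor markers negative in 17 of 20 (-0.35, Pdgfra -0.91 ± 0.27). Immediate early and heat shock genes were lower (-0.33, 10 of 22 lower adjusted over the list alone, with the heat shock gene Hspa1b at -1.33 ± 0.28), as were adipogenesis repressors (-0.53, 6 of 13, Klf2 -0.97 ± 0.21) and erythroid markers (-1.38, 7 of 7 negative, with the haem synthesis gene Alas2 at -1.69 ± 0.64). Cholesterol synthesis was higher (0.48, 3 of 20 adjusted over the list alone), as was triglyceride synthesis and uptake (0.41, with the fatty acid carrier Fabp5 at 2.23 ± 0.64). These 7 lists had adjusted p = 0.632 with an estimated correlation. Inflammatory genes (0.29, 2 of 27 adjusted over the list alone, with the neutrophil chemokine Cxcl2 at 1.64 ± 0.31) had adjusted p = 0.675 with an estimated correlation, and oxidative phosphorylation (0.20, Cox4i1 0.47 ± 0.15) had adjusted p = 0.741 with an estimated correlation. Without the low-fat control library, mature adipocyte markers (0.62), triglycerides (0.35) and cholesterol synthesis (0.28) did not pass. Without the low-fat stress library, erythroid markers (-0.49), inflammatory genes (0.21) and oxidative phosphorylation (0.15) did not. Triglycerides (0.40) were also lost without control high-fat library 4, and inflammatory genes (0.20) without stress high-fat library 1. Adjusted over the list alone, 0 members passed in the adipocyte, progenitor, erythroid, triglyceride and oxidative phosphorylation lists.

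For diet, edgeR called 0 of 20217 genes, with 3063 at an unadjusted p below 0.05 (2456 with the near-identical pair as 1 library) and a smallest adjusted p of 0.0653, whereas DESeq2 called 752 (461 higher, 291 lower) and limma on FPKM 3. fry called 0 lists (smallest adjusted p = 0.324), and camera 13 in place of 11 with the near-identical pair as 1 library. Each low-fat group is 1 library, so most of the spread was measured among the high-fat libraries, and edgeR called 62 genes without control high-fat library 4 and 2 without control or stress high-fat library 2. After Mmp12 and Slc6a2, the smallest p-values were those of Serpinb6b (2.43 ± 0.39), Trim59 (1.35 ± 0.20), the redox regulator Txnip (-0.95 ± 0.14) and Zfp395 (-0.85 ± 0.14). Lep was 2.43 and 2.40 CPM on the low-fat diet and 24.2 ± 15.4 and 32.9 ± 33.0 on the high-fat diet (3.60 ± 1.25, adjusted p = 0.249). Nr3c1 (-0.39 ± 0.11), Pnpla2 (0.67 ± 0.18), Gpd1 (1.18 ± 0.36), Plin1 (1.13 ± 0.39), Adipoq (1.64 ± 1.09), Pparg (0.67 ± 0.34), Lipe (0.39 ± 0.30), Aqp7 (-0.79 ± 0.51), Hsd11b1 (0.35 ± 0.46) and Nr3c2 (0.01 ± 0.35) did not pass.

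On the low-fat diet there was 1 library per group, so the stress difference there has no replicate check and compares 2 libraries, not the conditions. The steroidogenic gene Hsd3b1 had 258 counts in the stress library and 0 in the control library, at least 100.1-fold higher against a floor of 3 counts in the library, and Cyp11a1, which starts steroid synthesis, was 19.2-fold higher (480 counts against 27). Upk3a, a uroplakin of the bladder lining, was 10.9-fold higher, the basal epithelial factor Trp63 6.62-fold and the cadherin Fat2 5.82-fold. The immunoglobulin segments Igkv5-39 (26.9-fold), Ighg3 (8.49-fold), Ighv9-3 (6.09-fold) and Ighg2b (5.52-fold) and the chemokine Cxcl5 (7.19-fold) were lower. Of 9729 genes with at least 10 CPM in either library, 242 differed at least 2-fold, 179 higher and 63 lower, but with FPKM plus 1 it was 55 higher and 57 lower of 4229. Endothelial (median log2 ratio 1.5), mesothelial (1.43) and mural cell markers (1.02) lay at percentile 100 of 10000 random lists. So did erythroid (0.68), mature adipocyte (0.46) and macrophage markers (0.33), de novo lipogenesis (0.42) and triglyceride synthesis and uptake (0.29), while B cell markers (-1.11) and the interferon response (-0.51) lay at percentile 0. The random genes were drawn independently, while members of a list can vary together. For endothelial markers the estimated correlation was 0.62 in high-fat preadipocytes. These percentiles therefore do not measure chance. Nr3c1 (0.12), Nr3c2 (0.19), Pnpla2 (0.17), Plin1 (0.31), Lep (-0.02), Pdgfra (-0.22), Hsd11b1 (-0.59), Pparg (0.56) and Lipe (0.67) differed less than 2-fold, as did Gpd1 (0.80), while Adipoq (1.03) and Aqp7 (1.2) were more than 2-fold higher. Across 9722 genes the log2 stress difference on the low-fat diet and that on the high-fat diet had a Pearson correlation of -0.298 and a Spearman correlation of -0.02, where genes are not independent replicates. The sign was the same in 49.6 percent, so neither ranks nor signs show opposed effects. Some epithelial genes, picked after their values were seen, lay far apart in opposite directions. Krt15 was 8.27 CPM in the low-fat control and 44.3 CPM in the low-fat stress library. It was 299 and 304 CPM in the near-identical high-fat control pair and at most 0.49 CPM in the other high-fat preadipocyte libraries. Whether such genes set the Pearson value was not tested.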

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

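The test whether a lower share of progenitor cells raised the markers of every other cell type, the macrophage covariate and the count of splits that keep the near-identical pair on 1 side were chosen only after the results were seen. The other tests here were laid down before their own results were seen, some of them for patterns already noticed in these data. Effects of stress that differed between mature adipocytes and preadipocytes and values of 1 library far from the other 3 of its group stood out. With an adjusted p of at least 0.241 with an estimated correlation for every list, the interactions rest on the preset correlation.

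Thermogenic genes had the highest median interaction, 2.62, from a median of 1.59 in mature adipocytes (Ucp1 132 to 304 CPM under stress, 0.48 to 45.3 CPM in controls). Besides Ucp1, Dio2 and Ppargc1a, the members overlapped between the groups in mature adipocytes. Cidea, for example, was 30.3 CPM in control library 2 and 25.7 CPM in stress library 3. Scores of the list there (mean log2 CPM) were 1.70, 3.39 and 0.687 in control adipocytes and 3.84, 4.36 and 3.96 under stress. Loss of rare transcripts in the 2 low-complexity control libraries would have moved matched genes alike, yet the list lay at percentile 100 of 10000 random lists of the same expression, whose highest median was 0.62. This argues only weakly against that loss as the whole cause. The random genes were drawn independently, while the list's members vary together (estimated correlation 0.26), and expression was matched over all 6 libraries. Brown fat tissue in the stress fraction stays open: 0 of 5 brown fat genes were higher in every stress library than in every control library, but Zic1 and Lhx8 were near 0 throughout and the median of the 5 genes in these libraries was 0.75 CPM. Only 1 of the 10 splits of the 6 libraries, the real 1, gave the list so small a p (7.84e-12, against 8.60e-09 in the next), but 10 splits are too few for a share under 0.05. That stress itself browned the adipocytes on the high-fat diet is a hypothesis that stays open and was not tested apart from these.

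Macrophage markers (interaction -0.94) and cell cycle genes (-0.88, but 0.27 without control adipocyte library 2) moved together over 9 preadipocyte samples, the near-identical pair counted as 1 and all taken as independent, which the labels do not establish. Among 3 relations they had Pearson's r = 0.902 (permutation p = 0.00113, adjusted 0.00170) and Spearman's rho = 0.917 (permutation p = 0.00127, adjusted 0.00287), with r = 0.845 without the 2 samples farthest from the median and 0.878 in the 7 high-fat samples, while macrophage and progenitor markers went apart (r = -0.986, permutation p = 7.00e-05, adjusted 0.000210; rho = -0.900, permutation p = 0.00191, adjusted 0.00287; r = -0.984 without the 2 farthest and -0.982 in the high-fat samples). A lower progenitor share raising every other type alike is argued against as the whole cause, since endothelial minus macrophage scores had a slope of 3.34 ± 0.86 on the progenitor score (2.91 ± 0.97 in the high-fat samples; for B cell minus macrophage scores 2.61 ± 0.92 and 2.29 ± 1.19, the last within 2 standard errors of 0). Macrophage genes outside the marker list went with the cell cycle score (rho = 0.867, permutation p = 0.00458, adjusted 0.00458; r = 0.868, permutation p = 0.00176, adjusted 0.00176; 0.797 without the 2 farthest and 0.826 in the high-fat samples), but they follow the marker score at r = 0.988, so this repeats the first relation and decides nothing. A varying share of partly dividing macrophages in the sorted fraction may account for the 2 lists, as a hypothesis, though with the macrophage score as a covariate the cell cycle median for stress in preadipocytes was 0.22 (0.85 before) and still passed, and the effect of stress on macrophages stays open too, untested.

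The other lists that differed between the cell types were endothelial markers (1.54), B cell markers (1.34), erythroid markers (1.58), extracellular matrix (-0.56), de novo lipogenesis (0.37), adipogenesis repressors (0.76) and inflammatory genes (-0.50).

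Among the 4 stress high-fat preadipocyte libraries, 1 of 32 list scores and 9 of 114 named genes had 1 library far from the rest, where Dixon's test at the 95 percent critical value marks about 1 in 20 by chance; the genes are not independent of one another. Library 1 stood at 9.06 for immediate early and heat shock genes (others 8.52 to 8.53, mean log2 CPM). In CPM, library 2 stood at 24.9 for Cd163 (others 165 to 221), 6.59 for Ovgp1 (2.63 to 2.71), 18.1 for Dusp6 (36.0 to 38.0) and 13.8 for Slc6a2 (7.61 to 7.98). Library 3 stood at 1.31 for Krt18 (23.6 to 29.8). Library 4 stood at 15.5 for Plin1 (35.3 to 38.6), 197 for Ccl11 (532 to 581), 42.8 for Wt1 (132 to 161) and 3.78 for Acacb (6.72 to 7.08).

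Other splits of the samples show what chance and sample structure give. For stress in preadipocytes, 16 of the 35 splits of the 8 libraries gave at least the 12 lists of the real split, so chance is not excluded for the lists. A real count of 0 genes is met by any split (35 of 35), so the genes decide nothing. These splits take the near-identical pair as 2 samples; of the 15 that keep the pair on 1 side, 7 gave at least 12 lists. The highest other split called 340 genes; it set control libraries 1 and 3 with stress libraries 3 and 4, the 4 with the highest macrophage scores and the 2 closest pairs within a group (coefficients of variation 0.0427 and 0.205), and points to a structure of the samples that does not follow the groups. The highest other count of lists was 18. In mature adipocytes 10 splits are too few for a share under 0.05: 9 gave at least the 7 lists of the real split (highest other 18), and its 0 genes are met by any split (10 of 10, highest other 0). For the cell types 1 of 100 splits, the real 1, gave as many as 11372 genes (highest other 4960, from a split that kept 5 of the 6 adipocyte libraries together), so chance is excluded. For the interaction 54 of 100 drawn splits gave at least 10 lists (highest other 23), so chance is not excluded for the lists. Its 0 genes are again met by any split (100 of 100), and the 1148 genes of the highest other split point to sample structure.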

How the results depend on the processing

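Alternatives chosen only after the data were seen were the near-identical pair as 1 library, the 2 stress preadipocyte libraries with the highest macrophage scores left out, a macrophage score as a covariate, and the 2 low-complexity control adipocyte libraries left out, which leaves 1 control adipocyte library whose spread cannot be measured; the cause of a difference was not tested unless given. Of 205 values of the counts under alternatives, 166 equalled the main count or lay within a fixed ratio of it, 11 were lower and 28 higher. Only sizes were compared, so no count could be labelled as reversed. Of 4211 values of named genes, 4112 kept sign and call, or changed sign by at most 1 standard error without passing in either fit. A further 18 lost their call, 58 gained one and 23 reversed in sign.

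The cell type count ran from 10624 to 11851 with each library left out. With controls only it was 7739 and with stress libraries only 8201, fits of fewer samples, and 0 genes called in any alternative lay in the opposite direction. The count for stress in preadipocytes was 27 with DESeq2 and 0 with each library left out. In mature adipocytes it was 51 with no filter, 9 with DESeq2 and 0 to 9 with each library left out. The interaction gave 25 with DESeq2 and 0 to 3 with each library left out. Diet gave 752 with DESeq2, 1 with no filter, 3 and 1 with limma on FPKM plus 1 and plus 0.1, 27 with limma and no filter, 7 without the 2 macrophage-rich libraries, 9 with the macrophage covariate and 0 to 62 with each library left out. In simulated data DESeq2 made 38 to 63 false calls where edgeR made 0 to 8. It also recovered more of the genes changed 4-fold, for example 90.0 percent against 62.0 in the diet design, with 63 false calls there. The false calls in the simulation therefore do not show that the further DESeq2 calls are false. The low-fat pair gave 1146 genes at 1 CPM or more, a wider set, and 112 with FPKM plus 1 (55 higher and 57 lower, where 179 and 63 were higher and lower before).

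With the replicate number as a block, preadipocytes gave 1 gene for stress and 2 for diet, and the cell type count was 10063. For mature adipocytes and the interaction the block gave 0 genes. Samples with the same number did not deviate together in every pair (3 of 4 correlations above 0.1 for stress in preadipocytes and at most 1 of 3 elsewhere). Pairing by number stays open: the labels do not say, and Upk1a was high in high-fat control libraries 1 and 3 of both cell types. With the block, endoplasmic reticulum stress, triglycerides and erythroid markers lost their call in mature adipocytes. B cell markers and adipogenic transcription factors lost theirs for cell type. Lost in the interaction were lipogenesis, cell cycle, repressors and macrophage markers, and for diet immediate early genes, cholesterol synthesis and oxidative phosphorylation.

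The lists called with an estimated correlation numbered 0 for stress in preadipocytes, 0 for mature adipocytes, 5 for cell type, 0 for the interaction and 0 for diet. In mature adipocytes 11 lists passed with no filter, 11 at 1 CPM, 13 with 1 surrogate variable, 12 without the low-complexity libraries (1 control library against 3) and 3 to 13 with each library left out. For the interaction 16 passed with no filter, 16 without the low-complexity libraries and 5 to 15 with each library left out. Ranges with each library left out were 10 to 15 for stress in preadipocytes, 19 to 22 for cell type and 10 to 14 for diet. Endothelial (-1.79 to -1.10) and B cell markers (-1.44 to -0.84) kept their call in all 16 alternatives for preadipocytes, and thermogenic genes (1.05 to 2.54) in all 12 for mature adipocytes, 1 of which has a single control library. These tallies leave out the estimated correlation, with which none of these lists passed.

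Signs that turned were all of genes that did not pass. Without the 2 macrophage-rich libraries, the stress effect in preadipocytes was -0.16 for Birc5, 0.13 for Nr3c2, 0.48 for Hsd11b1, 0.76 for Adipoq, -0.08 for Pnpla2 and 0.04 for Lipe. Without the low-complexity libraries, the effect in mature adipocytes was 0.54 for Krt18, 0.55 for Adipoq, 0.59 for Pparg, 0.50 for Pnpla2, 0.66 for Lipe and 0.33 for Aqp7, and the interaction was 0.69 for Adipoq, 0.35 for Pnpla2 and 0.30 for Plin1. With limma on FPKM plus 0.1 the interaction of Adipoq was 0.60. The cell type value of Nr3c2 was 0.01 in stress libraries only. With each library left out, Pdgfra ran from -0.74 to 0.29 in mature adipocytes and from -0.82 to 0.21 in the interaction. Both highest values came without control adipocyte library 2. Without stress adipocyte library 2, Gpd1 was -0.05 in mature adipocytes (highest 0.59) and the interaction of Lipe -0.45 (highest 0.43). For diet, Lipe ran from -0.05 to 0.94 and Aqp7 from -1.64 to 0.55, lowest and highest without 1 or the other low-fat library. Rare transcripts are least sampled in control adipocyte library 3 (14182130 counts, 15344 genes detected, 0.637 genes with 1 to 5 counts per gene with 6 to 15) and library 1 (21995111 counts, 18091 genes, 1.15), so depth alone does not set this limit.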

Other observations

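The test whether 1 library was read or deposited 2 times was chosen only after its result was seen, and the epithelial genes below were picked after their values were seen. The bladder and stratified epithelial genes Upk1a, Upk3a, Krt15 and Cldn4 differed widely between libraries of 1 group. Upk1a, a uroplakin of the bladder lining (ENSMUSG00000006313, chromosome 7, 30603092 to 30612847), was 140 and 144 CPM in control high-fat preadipocyte libraries 1 and 3, 67.4 and 26.1 CPM in control high-fat adipocyte libraries 1 and 3, 25.4 CPM in the low-fat stress library and 0.15 to 5.84 CPM in the other 11. The basal keratin Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) was 151 and 144 CPM in the preadipocyte pair, 12.1 and 9.90 in the adipocyte libraries of the same numbers, 52.1 in the low-fat stress library and 11.2 or less elsewhere. Krt15 was 299 and 304 CPM in the pair, and the claudin Cldn4 263 and 256 CPM. The 2 adipocyte libraries are those of low complexity, and no explanation was tested.

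Immunoglobulin V genes together made up 313, 166, 320 and 308 CPM in control high-fat preadipocyte libraries 1 to 4, 241, 48.1, 84.4 and 109 CPM in the stress libraries, and 11.6 to 40.1 CPM in the mature adipocyte libraries.

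Across 13911 genes the stress effects in preadipocytes and in mature adipocytes had a Pearson correlation of 0.083 and a Spearman correlation of -0.015, and 49.4 percent had the same sign; genes are not independent replicates.

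Control high-fat preadipocyte libraries 1 and 3 were nearly identical, with a coefficient of variation of 0.0427 where the other pairs of a group gave 0.205 to 0.567. That 1 library was read or deposited 2 times is argued against by the 7.01 percent of genes (1209 of 17241) that differed between them, more than counting allows. Both may be samples of 1 animal or 1 pool of cells: their immunoglobulin V profiles, which differ from mouse to mouse, correlated at 0.942 across 122 genes, where the highest other pair of high-fat preadipocyte libraries gave 0.430. The pair already agreed over all genes (Spearman correlation 0.993), so a high value for these genes follows from that. It cannot tell 1 animal or pool from 1 RNA sample processed 2 times. The labels do not say which animals the libraries came from, and no biological explanation was tested.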
